A study of Sus scrofa and Rattus norvegicus with 6 samples.

How the data were processed

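RNA was measured in 6 libraries, 3 from pig and 3 from rat, prepared from adherent cultures of cells taken from around the central canal of adult spinal cord. Per the labels' protocols, the cultures grew without serum in a neural progenitor medium with EGF and FGF2 and received no treatment, polyadenylated RNA was made into strand-specific libraries, and single-end reads of 150 bases were sequenced on a NovaSeq 6000. Groups were taken from the sample titles, which give the species and a replicate number. The labels do not say whether the 3 libraries of a species came from separate animals or cultures, so the p-values and SDs measure only the spread between these libraries, which may be technical.

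The authors quantified transcripts with Salmon (version 1, per the submitters' processing notes) against Ensembl 104 transcript models, per the series' design text. Each deposited file holds 1 library and gives, per the file headers, the length, the effective length, the TPM and the estimated count of each transcript model. The deposited estimated counts are Salmon's assignment of reads to transcripts and need not be whole. The deposited TPM values divide those estimated counts by the effective length and are scaled to the same total in each library over all transcript models of the species. The submitters' processing notes also name FastQC, MultiQC, fastp, Trim Galore and DESeq2, with no role or version, and list the build rn6 for the samples of both species. The pig build, the settings of Salmon and any filter are not given in the sources used here.

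The effective length matters for these values. Among models longer than 600 bases with no reads in any library of the species, the median of length minus effective length in library 1 was 251 bases in both species. Between 519 and 1697 models per library had an effective length above their own length, so the deposited effective lengths hold more than a subtraction of a fragment length. A model close to or shorter than the fragment length has a very small effective length, and each of its reads then adds many TPM.

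The files name transcripts by versioned Ensembl transcript identifiers and do not pair them with genes. Of the 62843 pig and 40103 rat identifiers, 0 were found in the gene-name tables used here, which cover pig gene identifiers (15623 of them) and pig RefSeq records. Gene names were not inferred from identifiers. Transcripts were therefore not summed per gene, and pig genes were not matched to rat genes. Before the data were examined, an edgeR comparison of pig with rat over genes with the same symbol, set tests of 30 fixed gene lists (among them neural progenitor, ependymal, astrocyte, oligodendrocyte, microglial, fibroblast and cell cycle genes), levels of the same lists within each species, and the correlation of expression between the species had been planned. None of these could be run without gene names, and no list has a result. A transcript-level model cannot compare the species, since no transcript is quantified in both. The rule for named genes could not be applied either. In its place, the 2 transcripts with the highest mean TPM in each species are named, which was decided after their values were seen.

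Values were read with pandas 2.3.3 in Python 3.11.15. A transcript was called detected at a TPM of at least 1 in all 3 libraries of its species. Composition was described per library by the share of the 1, 10 and 100 most abundant transcripts, by the share of models under 300 bases, and by the effective number of transcripts, which is the exponential of the Shannon entropy and equals the number of equally abundant transcripts with the same entropy. Each was computed on TPM and on estimated counts, which gives 10 measures. Pig and rat were compared with an exact two-sided permutation test of the difference in means over all 20 arrangements of the 6 libraries, with Benjamini-Hochberg adjustment over the 10 measures. The shares of 6 length classes in both units were tested in the same way, as a family of their own. The smallest p that 3 against 3 libraries allow is 0.1, so no such comparison can pass 0.05. TPM and detection counts also depend on the transcript models of each species, so a difference between the species includes the difference between their annotations.

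Agreement between libraries of a species was measured by Pearson's correlation of log2(TPM + 1) and Spearman's correlation of TPM across all transcripts, and by the common biological coefficient of variation (BCV) of edgeR 4.0.16 in R 4.3.3, estimated with an intercept alone, TMM factors and estimated counts rounded to whole numbers, over transcripts with a mean estimated count of at least 10. On simulated counts with the means and depths of the pig libraries over 27694 transcripts, a true BCV of 0.2 was estimated as 0.202 and a true BCV of 0.6 as 0.596. For the rat libraries over 18692 transcripts the estimates were 0.202 and 0.599. The simulations gave every transcript the same BCV and divided no reads between models. They therefore check the estimate only under those conditions, and not at the pig value of 0.857. Transcripts whose estimated counts were whole in all 3 libraries, within 0.001, were also taken alone, because a fractional count shows that reads were divided between models. A transcript was called apart in 1 library when its depth-scaled estimated count plus 1 was at least 4-fold above or below that of both other libraries. No pair of libraries held identical values. Over transcripts with at least 20 estimated counts in a pair, the squared difference divided by the value expected from counting noise averaged between 41.9 and 75.8 per pair, against 1 for counting noise alone. No 2 libraries therefore agreed within counting noise alone. The expected value leaves out the uncertainty in how reads were divided between models, which also raises the ratio. It therefore does not show whether the libraries came from separate cultures.

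Library totals were 28410384 to 41189880 estimated counts. Reads carry no molecular identifiers here, so counting precision from these totals covers counting error only. The alternatives tried were other TPM minimums, estimated counts in place of TPM, models under 300 bases left out, length minus 250 bases as effective length, thinning of all libraries to 28410384 counts, other normalizations and filters, matching of transcripts between species on length and mean count, a test within replicate numbers, and leaving out each library in turn. The other TPM minimums and the leaving out of libraries for the detection counts were fixed before the data were examined. The remaining alternatives, and the composition and scatter measures themselves, were chosen after it was known that the files carry no gene names.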

Results

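The transcriptomes of cultured cells from around the central canal of the adult spinal cord were compared between pig and rat. The central canal is lined by ependymal cells, which carry motile cilia and lie next to other glia. The cultures were grown as adherent cells with EGF and FGF2, growth factors commonly used to expand neural progenitors. There were 3 pig libraries and 3 rat libraries, with no treated or control arm, and species was the only contrast in the labels. Pig libraries 1, 2 and 3 held 37593182, 37554724 and 32211354 estimated counts, and rat libraries 1, 2 and 3 held 41189880, 37283828 and 28410384. The deposited tables list transcripts by Ensembl identifier and do not pair them with genes, so markers of ependymal cells, astrocytes, oligodendrocyte progenitors or other cell types were not analysed here.

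The first question was how much of each annotated transcriptome the cultures expressed. The pig cultures expressed 17631 transcripts at a TPM of at least 1 in all 3 libraries, which was 28.1% of the 62843 pig transcript models. The rat cultures expressed 14475 transcripts by the same criterion, or 36.1% of 40103 models. Transcripts without a read in any library made up 41.6% of the pig models and 41.5% of the rat models. Detected transcripts were longer than the annotation as a whole, with a median length of 2997 bases against 2867 in pig and 2118 against 1301 in rat. Long transcript models of 4000 bases or more were detected in 60.6% of cases in rat (2446 of 4033) and in 28.0% of cases in pig (5830 of 20856). Models under 300 bases were detected in 3.85% of cases in rat (257 of 6679) and in 4.68% of cases in pig (123 of 2629). These shares were not tested between the species, because the 2 annotations differ in size and in model length. Lengths divisible by 3, which coding-only models have and which chance gives in 33.3% of models, occurred in 48.5% of rat models and 37.7% of pig models.

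By estimated counts, a few transcripts took a larger share of the pig libraries than of the rat libraries. The 10 transcripts with the most estimated counts took 11.1% ± 0.919 (SD, n = 3) of the pig libraries and 6.24% ± 0.318 (SD, n = 3) of the rat libraries. The first 100 took 25.4% ± 1.15 in pig and 18.5% ± 0.262 in rat (SD, n = 3 each). The effective number of transcripts by estimated counts was 4201 ± 246 in pig and 4963 ± 57.6 in rat (SD, n = 3 each). In each of these 3 measures every pig library lay on the same side of every rat library, and the exact permutation test gave p = 0.1 two-sided (adjusted p = 0.125 over 10 measures), the smallest p that 3 against 3 libraries allow. In TPM the order was the same for the 10 most abundant transcripts, with 22.1% ± 1.76 in pig and 18.6% ± 1.76 in rat (SD, n = 3 each, exact permutation p = 0.1). With length minus 250 bases as the effective length, that difference turned to -1.37 percentage points. That setting gives models up to 250 bases an effective length of 1, and the first transcript alone then held 34.5% in pig and 31.0% in rat. The effective number by TPM was 1319 ± 157 in pig and 1596 ± 145 in rat (SD, n = 3 each), with overlapping libraries and an exact permutation p of 0.2, and the difference turned to 5.38 with length minus 250 bases. The first transcript alone ran the other way in TPM, with 6.89% in pig and 7.85% in rat (exact permutation p = 0.3). That difference turned to 3.50 percentage points with length minus 250 bases and to 1.98 without models under 300 bases, and it ranged from -0.44 without rat library 3 to -1.68 without rat library 2.

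**Figure D1:**
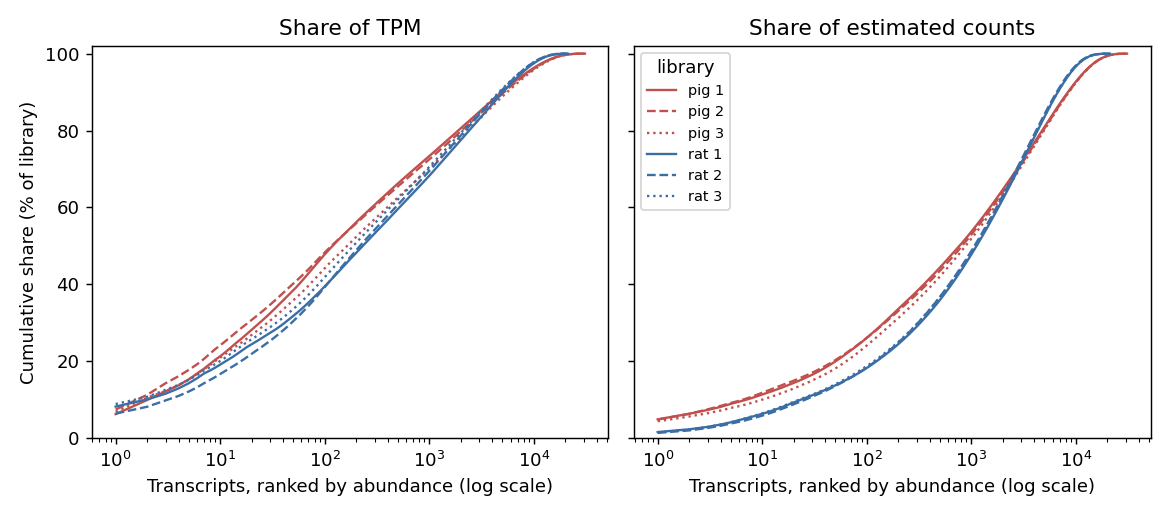
Cumulative share of each library (percent) against the number of transcripts ranked by abundance (log scale), by TPM on the left and by estimated counts on the right, with 1 line per library. By estimated counts the 3 pig lines lie above the 3 rat lines over the first 100 transcripts, where they reach 25.4% in pig and 18.5% in rat on average.

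In estimated counts, 3.23 of the 4.83 percentage points by which the first 10 transcripts differed between pig and rat came from the first transcript alone. ENSSSCT00000012075.4, a model of 2046 bases, held 4.74% ± 0.277 of the estimated counts of the pig libraries (SD, n = 3) and ranked first among pig transcripts by estimated count. Its level was 37078 ± 871 TPM (SD, n = 3), the second highest in pig. The highest-ranked rat transcript of each library held 1.51% ± 0.110 of the estimated counts (SD, n = 3), so the leading pig share was 3.14 times the leading rat share (exact permutation p = 0.1, n = 3 per species). ENSRNOT00000046108.3, a model of 681 bases, ranked second in rat both by TPM (17891 ± 1249, SD, n = 3) and by estimated count (0.703% ± 0.0565 of the library).

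The transcripts with the highest TPM were in both species short models of 204 bases. ENSSSCT00000019675.1 in pig reached 68880 ± 6047 TPM (SD, n = 3), or 6.89% of all TPM, and ENSRNOT00000046201.3 in rat reached 78495 ± 12874 TPM (SD, n = 3), or 7.85%. The same transcripts held 0.0439% ± 0.00351 of the pig estimated counts and 0.0682% ± 0.0124 of the rat estimated counts (SD, n = 3 each), and they ranked 249 in pig and 131 in rat by estimated count. The deposited effective length of both was 9 bases. The shares of the leading transcript in TPM overlapped between the species, with 6.89% ± 0.605 in pig and 7.85% ± 1.29 in rat (SD, n = 3 each, exact permutation p = 0.3).

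Short transcript models carried more of the rat TPM than of the pig TPM. Models under 300 bases held 20.8% ± 1.23 of the rat TPM and 12.5% ± 1.10 of the pig TPM (SD, n = 3 each), while they made up 16.7% of the rat models and 4.18% of the pig models. With length minus 250 bases as the effective length, which is set to 1 for models up to 250 bases, these shares became 65.5% in rat and 51.3% in pig. By estimated counts their share was 0.251% ± 0.0201 in rat and 0.0977% ± 0.00764 in pig. For both units the libraries of the species did not overlap (exact permutation p = 0.1, adjusted p = 0.125, n = 3 per species). Models of 4000 bases or more were 20856 of the 62843 pig models and 4033 of the 40103 rat models. They held 31.7% ± 1.88 of the estimated counts in pig and 22.5% ± 1.21 in rat (SD, n = 3 each). In TPM they held 8.55% ± 0.837 in pig and 4.58% ± 0.378 in rat. The exact permutation p was 0.1 for both units (adjusted p = 0.12 over the 12 shares of the 6 length classes). Models of at least 1000 and under 2000 bases were 12194 of the 62843 pig models and 9605 of the 40103 rat models. They held 23.3% ± 1.29 of the estimated counts in pig and 30.2% ± 0.628 in rat (SD, n = 3 each, exact permutation p = 0.1). In TPM their share was 26.0% ± 0.267 in pig and 26.5% ± 0.419 in rat (SD, n = 3 each, exact permutation p = 0.3).

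**Figure D2:**
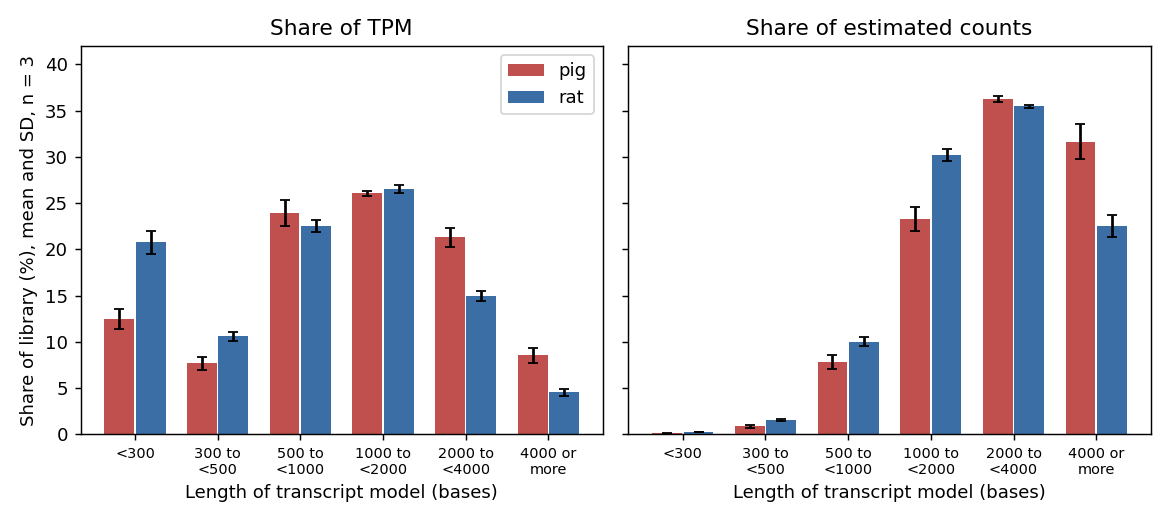
Share of the library (percent, mean with SD as error bars, n = 3 per species) held by transcript models of each length class (bases), by TPM on the left and by estimated counts on the right. Models under 300 bases hold 12.5% of the pig TPM and 20.8% of the rat TPM but 0.0977% and 0.251% of the estimated counts.

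Libraries of a species were compared with each other. By the common BCV over all tested transcripts, the pig libraries scattered more than the rat libraries. Pearson's correlation of log2(TPM + 1) across transcripts averaged 0.965 over the 3 pairs of pig libraries, with a range of 0.962 to 0.967, and 0.968 over the 3 pairs of rat libraries, with a range of 0.965 to 0.973. Spearman's correlation averaged 0.875 in pig (0.871 to 0.879) and 0.923 in rat (0.919 to 0.929). At a mean TPM of at least 1 the order of Pearson's means turned, to 0.915 in pig and 0.913 in rat, and Spearman's means lay closer together, at 0.905 and 0.918. These are correlations across transcripts, which are not independent replicates. The common BCV was 0.857 over 27694 pig transcripts and 0.517 over 18692 rat transcripts, a ratio of 1.66. Leaving out 1 library at a time gave ratios between 1.53 and 1.92. The BCV itself was lower in both species at a mean count of at least 100, with 0.540 in pig and 0.318 in rat. Among whole-count transcripts it was 0.404 in pig and 0.261 in rat, and among those with fractional counts 0.940 and 0.714. The ratio was 1.55 among whole-count transcripts, 1.32 among those with fractional counts and 1.23 among transcripts matched between the species on length and mean count. It was 0.990 among whole-count transcripts matched in that way, from 0.637 to 1.37 with 1 library of each species left out, and 0.957 among whole-count transcripts above 0 in all 3 libraries, a filter that itself removes scatter. The difference in BCV was not tested, since each species gives 1 estimate.

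Transcripts that stood apart in 1 library were counted in each species. On average 6.51% ± 0.604 of the tested pig transcripts (SD over 3 libraries) were at least 4-fold above or below both other libraries, with 1659 to 1986 transcripts per library. In rat the share was 3.46% ± 1.06 (SD over 3 libraries), with 515 to 873 transcripts per library, the highest in rat library 3, which was also the shallowest. These shares were not tested, because each library's share is measured against the other libraries of its species. Reads were divided between models more often in pig, where 15.8% of the tested transcripts (4378 of 27694) had whole estimated counts in all 3 libraries, against 49.9% in rat (9330 of 18692). Among whole-count transcripts the share apart was 2.43% ± 0.267 in pig and 1.36% ± 0.523 in rat (SD over 3 libraries). Among those above 0 in all 3 libraries it was 0.413% ± 0.299 in pig and 0.559% ± 0.212 in rat. Among transcripts with fractional counts the shares were 7.27% ± 0.713 and 5.54% ± 1.60, with overlapping libraries (SD over 3 libraries).

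**Figure D3:**
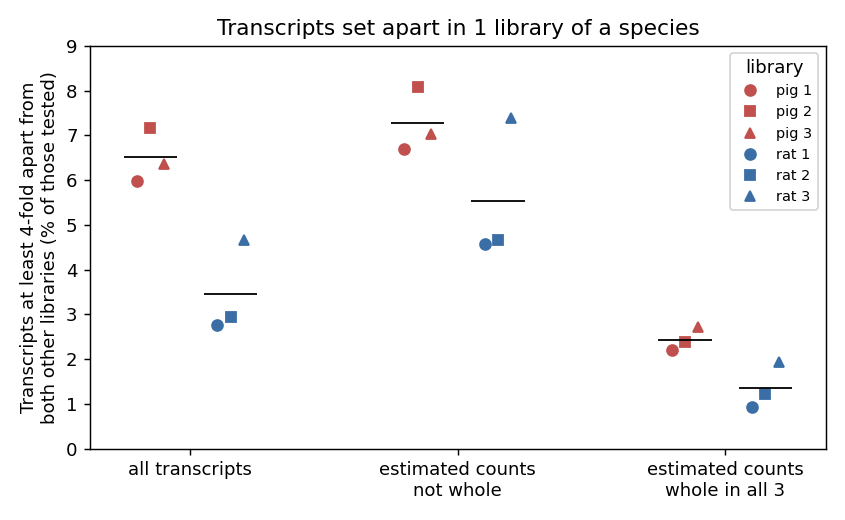
Percent of tested transcripts at least 4-fold apart from both other libraries of the species, with 1 point per library and a line at the mean of the 3 libraries, for all transcripts, for those with fractional counts and for those with whole counts in all 3 libraries. The mean is 6.51% in pig and 3.46% in rat over all transcripts, and 2.43% and 1.36% over whole-count transcripts.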

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

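No planned comparison between genes of pig and rat was run under any setting, because the files carry no gene names. This leaves out the normalization, tool, filter, length, unit, matching and threshold alternatives planned for it, those of the gene list tests and list levels, and those of the correlation between species. The detection counts stayed within 1.5 times their value under each alternative except a TPM of at least 5, which left 11065 pig transcripts. Without 1 library they ranged from 18359 to 18470 in pig and from 14794 to 15072 in rat. The remaining alternatives were chosen after the files had been seen. The share of the most abundant transcript was 0.96 percentage points lower in pig than in rat by TPM and reversed to 3.23 points higher by estimated counts, to 1.98 points higher without models under 300 bases, and to 3.50 points higher with length minus 250 bases. Without 1 library it ranged from -1.68 to -0.44. The last setting also reversed the 10 most abundant transcripts to -1.37 points and the effective number to a difference of 5.38, and it gives models up to 250 bases an effective length of 1. With a replicate block, which here compared libraries of the same replicate number although a number does not pair a pig with a rat, the exact sign-flip p was 0.25 for the 10 most abundant transcripts and 0.25 for models under 300 bases, the smallest that 3 pairs allow, and it was 0.5 for the most abundant transcript and for the effective number. The ratio of pig to rat BCV fell from 1.66 to 0.957 among whole counts above 0, to 0.990 among whole counts matched on length and mean count, to 1.23 after that matching alone and to 1.32 among fractional counts. It ranged from 1.53 to 1.92 without 1 library. The mean Pearson correlation became 0.941 in pig and 0.953 in rat with a pseudocount of 0.1, and 0.915 and 0.913 at a mean TPM of at least 1, where the order of the species turned. Spearman's mean became 0.905 in pig and 0.918 in rat at that TPM. Without 1 library Pearson's r ranged from 0.962 to 0.967 in pig and 0.965 to 0.973 in rat, and Spearman's rho from 0.871 to 0.879 and 0.919 to 0.929. The share of transcripts apart in 1 library was 2.43% in pig and 1.36% in rat for whole counts, 0.413% and 0.559% for whole counts above 0, and 5.41% in pig at 8-fold. The cause of the difference in the share apart was not tested otherwise. Among the composition measures, thinning to equal totals was tried for TPM only. The differences were then -0.98 and 3.47 points for the first 1 and 10 transcripts. The ratio of pig to rat BCV from thinned estimated counts was 1.70.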

Other observations

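The tests of mitochondrial lengths, of small effective lengths, of whole counts combined with matching, of whole counts above 0 and of matching with libraries left out were chosen only after results had been seen. Of the lengths among the 20 transcripts with the highest mean TPM in pig, 6 also occurred among the first 20 in rat, an overlap not tested against chance. In pig, 6 of the first 20 had exactly the length of 1 of the 13 mitochondrial protein-coding genes in pig RefSeq (assembly Sscrofa11.1). In 100000 random draws of 13 lengths from the detected transcripts, the median was 0 matches and the maximum 3. In rat, 7 of the first 20 had 1 of these pig lengths, against a maximum of 4 in draws made in the same way. The draws were not matched on length. Detected transcripts had a median length of 2997 bases in pig and 2118 in rat. Of them, 123 of 17631 in pig and 257 of 14475 in rat were under 300 bases. Among the first 20 by TPM, 3 in pig and 7 in rat were that short. The draws can therefore understate chance matches between short lengths, and they do not measure how unlikely the matches are. The transcripts with a matching length held 13.3% ± 1.02 of the TPM and 2.77% ± 0.274 of the estimated counts in pig, and 14.4% ± 1.78 and 3.82% ± 0.299 in rat (SD, n = 3 each). It is a hypothesis that they may be mitochondrial messenger RNA, since a match of length does not identify a gene and an identifier table was not used here.

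The length matches were counted over models of any length, so they do not address why short models stand at the head of the TPM ranking. Division by a small effective length is an explanation for that, and it stays open. Of the 3 models under 300 bases among the first 20 pig transcripts by TPM, 0 stayed among the first 20 by estimated count, and of the 7 in rat also 0. At a given TPM, a model with a smaller effective length holds fewer estimated counts. This loss of rank therefore cannot separate a small effective length from real abundance. The median of the deposited effective lengths of these models was 9 bases in both species.

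The greater scatter of the pig libraries, with a BCV of 1.66 times that of the rat libraries, could be technical or biological. Library totals overlapped between the species, at 32211354 to 37593182 in pig and 28410384 to 41189880 in rat. Thinning to equal totals therefore had little difference to remove and was a weak test of depth. It gave a ratio of 1.70 (at least 1.47 when 1 library of each species was also left out). A single pig library standing apart is argued against by the lowest pig BCV without 1 library, still 1.49 times the highest rat value. The mix of lengths and mean counts alone as the whole cause is argued against by a ratio of 1.23 over 20 matched draws (at least 1.10 with 1 library of each species left out), although matching removed most of the excess. Reads shared between overlapping models stay open. The ratio was 1.55 among whole-count transcripts (at least 1.12 with libraries left out), which had been set down as evidence against them. But a count of 0 is whole even where another model took the reads. Without the 264 pig and 209 rat transcripts at 0 in a library the ratio was 0.957, a filter that also removes transcripts truly absent from 1 library. In both species the BCV was higher among fractional counts (0.940 in pig, 0.714 in rat) than among whole counts (0.404 and 0.261). Whole counts made up 15.8% of the tested transcripts in pig and 49.9% in rat. Part of the excess thus goes with the larger share of fractional counts in pig, which does not show that shared reads caused it. Among whole-count transcripts matched on length and mean count, 0 included, the ratio was 0.990 over 20 draws, but from 0.637 to 1.37 with 1 library of each species left out. Shared reads together with the mix of lengths and counts therefore stay open too, and a difference between animals or cultures stays untested.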
